A study of Mus musculus with 9 samples.

How the data were processed

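Total RNA was measured in C2C12 cells, an established mouse myoblast line, with whole-transcript exon arrays that carry separate probe sets for the exons of a gene. Per the labels' protocols, the cells were grown in serum-containing medium, transfected with a control siRNA or with an siRNA against Cugbp1 or Mbnl1, and lysed 48 h later. The labels' protocols give 100 ng of total RNA per array as the input for cDNA synthesis and biotin labelling. Groups and replicate numbers were taken from the sample titles, with 3 arrays in each of 3 groups. The sources used here do not say whether the replicates came from separate cultures, so every p-value measures only the spread between these arrays, which may be technical.

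The authors deposited a table with the intensity of 1195555 probe sets on each of the 9 arrays, on a linear scale. Per the submitters' processing notes, these values were made with RMA (a background correction, normalisation between arrays and summary over probes) in Affymetrix Expression Console, with genome build mm9. Software versions and the background option are not given in the sources used here. The median intensity was 43.6 to 43.8 on the controls and 42.3 to 42.9 on the 6 siRNA arrays, without overlap. The 25th percentile was 14.4 to 14.5 and 14.1 to 14.3, and the 75th 131 and 130 to 132. The values were log2-transformed and otherwise used as deposited. All 9 columns were matched to a sample by its labels. No depth of sequencing applies to arrays, and the number of arrays limits the precision.

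Probe sets were named from the array's GEO platform annotation, which gave exactly 1 gene symbol to 316997 probe sets and several symbols to 6571, and did not list 871987. The last are unnamed here, and no gene was named from a probe set with several symbols. Of the 22264 symbols, 17988 were current in a RefSeq gene table for assembly GRCm38.p6, 4213 were updated through its synonyms and 63 were kept as given. No coordinates were used. Probe sets were kept when their mean over all 9 arrays reached the 75th percentile of all probe sets, a log2 value of 7.00 (intensity 128). This left 298889 probe sets, 168803 of them with 1 symbol. It kept 53.3% of the probe sets with 1 symbol and 14.8% of the unnamed ones. A gene was tested when at least 3 of its probe sets were kept, which gave 12646 genes with a median of 10 probe sets. The gene value on each array was the Tukey median polish of its kept probe sets.

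Gene values were fitted with limma 3.58.1 in R 4.3.3 (data.table, version 1.17.8), with a mean per group over all 9 arrays in the same fit, so that the groups shared 1 estimate of the spread. Contrasts were Cugbp1 siRNA minus control, Mbnl1 siRNA minus control and Cugbp1 siRNA minus Mbnl1 siRNA, each moderated with eBayes and adjusted with Benjamini-Hochberg over genes. A gene was called at an adjusted p under 0.05. The third contrast tests whether a gene responded differently to the siRNAs. Both contrasts against control use the same 3 control arrays, so the overlap of called genes was set beside 100 simulated pairs of unchanged groups that shared those controls and beside the overlap of independent lists.

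Exon usage was tested with limma's diffSplice on the 158713 kept probe sets of the 11374 genes with at least 4 of them. It compares the change of a probe set with that of the rest of its gene, and calls were made at a Benjamini-Hochberg adjusted p under 0.05 over probe sets. A call says that a probe set departed from its gene, not which exon or transcript end it covers, since no coordinates were used.

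The gene and exon-usage steps were tested on simulated data before use. The simulation copied the comparison of Cugbp1 siRNA with control, with 12646 genes and 162529 probe sets, and changed 67 genes 1.2-fold, 67 genes 1.5-fold and 66 genes 2-fold, and single probe sets of other genes 1.5-fold, 2-fold and 3-fold. With noise as estimated from the arrays, the gene test recovered 32.8%, 89.6% and 98.5% of them, and 9 of its 156 calls were false. With variances shrunk towards a common value, a second noise model added after the first had been seen, it recovered 28.4%, 94.0% and 100%, with 11 false calls of 159. In the same simulation diffSplice made 691 calls under the first noise model, 493 of them in genes with no change, and 311 under the second, 142 of them in such genes. For that reason an alternative was added after the data were seen: the difference between a probe set and its gene value on the same array was tested in limma with a mean-variance trend, so that each probe set kept its own variance. That test made 141 and 167 calls, of which 2 and 5 were in genes with no change. It recovered 34.3% of probe sets changed 1.5-fold, 77.6% of those changed 2-fold and 97.0% of those changed 3-fold under the first noise model, and 52.2%, 91.0% and 100% under the second. The comparison of exon usage between the siRNAs was also added after the data were seen.

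Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 16 lists within a contrast. Camera with an estimated correlation and limma's fry were run beside it. The lists covered the CELF and MBNL family, other splicing regulators, the mRNA decay machinery, immediate-early and short-lived mRNAs, myogenic regulators, sarcomere and muscle differentiation, cell cycle and DNA replication, the interferon response, extracellular matrix, cholesterol synthesis and uptake, p53 targets, the unfolded protein and integrated stress response, TGF-beta and BMP signalling, adipocyte and osteoblast markers, markers of haematopoietic, endothelial, epithelial and neural cells, and genes with exons regulated by MBNL or CELF proteins in myotonic dystrophy. Some genes stand on more than 1 list, such as Mbnl1 and Cdkn1a. Whether listed genes were over-represented among genes with called probe sets was tested with 10000 random sets of genes, drawn among genes with like numbers of probe sets.

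The genes named in the text were taken from those that a rule picked. The text leaves out many of the list members and some of the listed genes for exon usage that the rule picked, and 1 gene among the largest changes is not reported here. Celf1 and Mbnl1 were always named. For each contrast against control, the 10 largest rises and the 10 largest falls were taken among called genes whose 3 treated arrays all lay outside the range of the 3 control arrays, and 5 each for the contrast between the siRNAs. From each list, up to 4 members with the smallest p were taken, plus all members past the threshold where these were 6 or fewer. For exon usage, the 10 probe sets with the smallest diffSplice p in different genes were taken per contrast, plus up to 8 listed genes with a called probe set. Probe sets named from the own-variance test, and the gene families in the closing section with their members, were chosen after their values were seen.

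The groups, contrasts, tests, filter, gene lists, naming rule and most alternatives were fixed before the data were examined. Alternatives were the replicate number as a block, the mean of the probe sets as the gene value, no filter and filters at the median and the 85th percentile, quantile normalisation repeated over the kept probe sets, centring each array on the median, a trended and robust variance, fits of only the groups compared, array weights, a minimum change of 1.5-fold, called genes left out of the exon-usage test, other set tests, and each array left out in turn. Alternatives chosen after seeing the data were the own-variance exon-usage test, a minimum of 1.5-fold for exon usage, all runs of exon usage between the siRNAs, a covariate made from probe sets of tissue-restricted genes, and gene lists without the targets Celf1 and Mbnl1. An earlier test of a shared intensity trend was dropped because its simulated range, correlations from -0.74 to 0.98 across genes, left its bound uninformative, and a test on tissue-restricted genes, written after the overlap had been seen but before its own value, was used in its place. A planned test of GU-rich and YGCY motifs in 3' UTRs was not run, because transcript sequences were not used here.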

Results

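RNA from C2C12 cells, a mouse myoblast line used to study muscle cells in culture, was measured on 9 exon arrays 48 h after transfection. The cells had received a control siRNA, an siRNA against Cugbp1 or an siRNA against Mbnl1, with 3 arrays per group. Cugbp1 is the older name of Celf1. CELF1 and MBNL1 are RNA-binding proteins that control alternative splicing and the stability of mRNAs, and both are disturbed in myotonic dystrophy. After the filter on weak signals, 12646 genes were tested from 168803 probe sets. Median intensities of the arrays lay between 42.3 and 43.8, and the number of arrays limits the precision. The first principal component of the gene values, with 54.2% of the variance, separated the control arrays (-14.5 to -16.7) from the siRNA arrays (2.16 to 11.2). The second, with 17.5%, separated Cugbp1 siRNA (-7.30 to -10.2) from Mbnl1 siRNA (6.40 to 7.42).

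**Figure D1:**
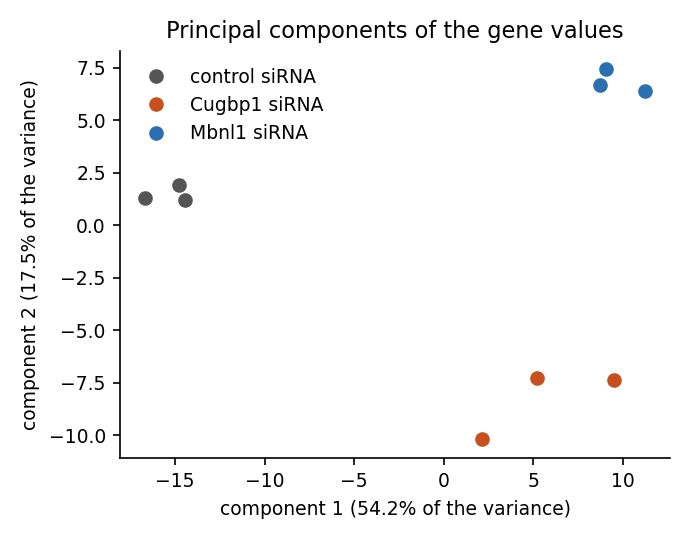
Principal components of the gene values, with 1 point per array coloured by siRNA and the share of the variance on each axis. Component 1 (54.2%) parts the 3 control arrays from the other 6, and component 2 (17.5%) parts the arrays of the targeting siRNAs.

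The targeted genes were low on every array that should show it. Celf1 stood at 10.13 ± 0.02 in control cells, 8.67 ± 0.12 after Cugbp1 siRNA and 10.06 ± 0.06 after Mbnl1 siRNA (log2 intensity, mean ± SD, n = 3). The 3 Cugbp1 siRNA arrays read 8.60, 8.60 and 8.81, and the 3 controls 10.11, 10.14 and 10.14. Celf1 fell by 1.46 on the log2 scale, which left 36.4% of the control level (95% interval 33.2% to 39.8%; limma with Benjamini-Hochberg, adjusted p = 9.01e-07). Mbnl1 stood at 11.45 ± 0.01 in control cells, 11.50 ± 0.06 after Cugbp1 siRNA and 10.11 ± 0.07 after Mbnl1 siRNA (n = 3). The 3 Mbnl1 siRNA arrays read 10.05, 10.10 and 10.18. Mbnl1 fell by 1.35 on the log2 scale, which left 39.3% (36.5% to 42.4%; limma with Benjamini-Hochberg, adjusted p = 3.97e-07). Neither siRNA changed the other target past the threshold: Celf1 differed by -0.07 after Mbnl1 siRNA (adjusted p = 0.345) and Mbnl1 by 0.05 after Cugbp1 siRNA (adjusted p = 0.471). Of the 25 Celf1 probe sets, 24 were lower after Cugbp1 siRNA, 20 of them at least 2-fold. Of the 23 Mbnl1 probe sets, 20 were lower after Mbnl1 siRNA, 15 of them at least 2-fold.

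**Figure D2:**
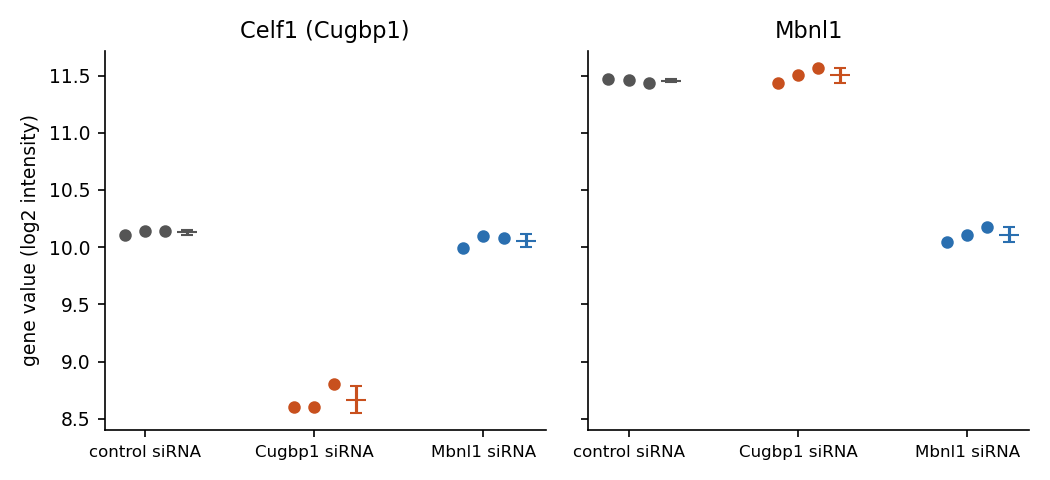
Gene values of Celf1 and Mbnl1 (log2 intensity) on each array, with the mean and SD of each group of 3 beside the points. Celf1 was 8.60 to 8.81 after Cugbp1 siRNA against 10.11 to 10.14 in controls, and Mbnl1 was 10.05 to 10.18 after Mbnl1 siRNA.

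The comparison of Cugbp1 siRNA with control asks which transcripts changed after that siRNA. Alone it cannot tell loss of CELF1 from a difference between the control arrays and all siRNA arrays, such as the first principal component showed. Large rises were in Prr9 (log2 change 1.5, SE 0.06; limma with Benjamini-Hochberg, adjusted p = 9.01e-07) and in Nmnat2, an enzyme of NAD synthesis (1.2, SE 0.06, adjusted p = 4.47e-06). Acp1, a low-molecular-weight tyrosine phosphatase, followed (1.01, SE 0.04, adjusted p = 9.01e-07). Aspn, a small proteoglycan of the matrix, rose by 1.23 and Ppargc1a, a coactivator of mitochondrial biogenesis, by 1.00. Zfp101 rose by 1.00, Lrrc4c by 0.98 and the neurotrophin receptor gene Ngfr by 0.90. H4c12 rose by 1.43, but it is 1 of many near-identical histone genes and its signal is uncertain. Besides Celf1, the membrane protein gene Tmem123 fell by 0.79 (SE 0.04, adjusted p = 1.12e-05) and Sgms2, a sphingomyelin synthase, by 0.77 (SE 0.06, adjusted p = 5.36e-05). The other large falls were in Eomes (-0.85), Rspo2 (-0.80), Abca12 (-0.79), Lypd9 (-0.76), Slc25a47 (-0.75), Mfap4 (-0.74) and Iba57 (-0.73). Each of these 7, and the rises of Aspn and Lrrc4c, rest on 3 or 4 probe sets, and without the filter on weak signals Abca12 (-0.08), Rspo2 (-0.05), Eomes (-0.21), Slc25a47 (-0.26) and Lrrc4c (0.34) no longer passed. The controls of Aspn (6.86 ± 0.20) and Lrrc4c (6.79 ± 0.50), and Abca12 after Cugbp1 siRNA (6.90 ± 0.35, n = 3), lay below the filter's threshold, so the size of these changes is uncertain.

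Across all genes, limma with Benjamini-Hochberg called 4893 of 12646 after Cugbp1 siRNA, 3293 higher and 1600 lower, most of them by little: the median size of a called change was 0.25. At least 1.5-fold changes numbered 108 (84 higher and 24 lower). In 48.8% of genes the Cugbp1 siRNA and control arrays did not overlap, against 10% by chance. The balance of rises and falls depended on the scaling of the arrays: 1650 were higher and 2731 lower with quantile normalisation repeated, and 1366 and 3206 with each array centred on its median. The median change of all genes was 0.05 as deposited, -0.02 with repeated normalisation and -0.04 with centring; for Mbnl1 siRNA it was 0.04, -0.03 and -0.06. Signals that a myoblast is not known to make moved as well. In 192 probe sets above the filter from 143 genes for odorant, pheromone and taste receptors, beta-defensins and keratin-associated proteins, the median change was -0.18 after either siRNA, and limma called 12.5% of them after Cugbp1 siRNA and 14.1% after Mbnl1 siRNA, against 14.9% and 21.5% of the other named probe sets. With a covariate made from these probe sets, a choice made after the data were seen, limma with Benjamini-Hochberg called 0 genes after either siRNA (1543 and 1391 at an unadjusted p under 0.05). The covariate was 94.2% control against the rest. The median SE grew from 0.06 to 0.20 and 0.22, and the median size in the called genes went from 0.25 to 0.18 and from 0.27 to 0.20.

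Of 48 splicing regulators outside the CELF and MBNL family, 22 rose after Cugbp1 siRNA and 2 fell (26 and 2 adjusted over the list alone), among them the RNA-binding protein genes Tia1 (0.59) and Khdrbs3 (0.59) and the splice-site factor gene U2af1 (0.24). Camera called the list higher (adjusted p = 0.00406; adjusted p = 0.658 with an estimated correlation), and 6 were called higher and 4 lower with centred arrays. Of 53 genes of the mRNA decay machinery, 20 rose (20 adjusted over the list alone), including the 5' exonuclease gene Xrn1 (0.84, SE 0.05), Zfp36l1 (0.46) and the deadenylase genes Pan3 (0.30) and Parn (0.27). The camera test gave an adjusted p of 0.0233 (adjusted p = 0.658 with an estimated correlation), and with centred arrays 7 were called higher and 5 lower. Within the CELF and MBNL family of 9, 5 fell and 1 rose (5 and 2 adjusted over the list alone): besides Celf1, Celf6 (-0.46), Celf3 (-0.34), Celf5 (-0.28) and Mbnl3 (-0.23) were lower and Celf2 (0.24) was higher. For this family camera gave an adjusted p of 0.0319 (adjusted p = 0.461 with an estimated correlation; 0.123 without the filter), but the call rested on the siRNA target. With Celf1 and Mbnl1 left out, a test added after the data were seen, the mean of the other 7 was -0.12 and the list was not called (camera, adjusted p = 0.177). After Mbnl1 siRNA the mean of these 7 was -0.09, and 0 of them were called between the siRNAs, so their changes were not particular to Cugbp1 siRNA. Of 64 genes with exons regulated by MBNL or CELF proteins in myotonic dystrophy, 22 rose and 8 fell (22 and 9 adjusted over the list alone), such as Trim55 (0.40), Itga6 (0.30), Mapt (-0.46) and Sorbs2 (-0.31). The list was not called (camera, adjusted p = 0.296). With centring 7 were called higher and 12 lower, and its median of 0.09 turned to -0.00.

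Of 21 genes of cholesterol synthesis and uptake, 10 rose after Cugbp1 siRNA (10 adjusted over the list alone), including the SREBP regulator gene Insig1 (0.38), Cyp51 (0.36) and the lanosterol synthase gene Lss (0.27). Camera called the list higher (adjusted p = 0.0257; adjusted p = 0.196 with an estimated correlation), and with centred arrays 5 were called higher and 1 lower. Of 26 genes of TGF-beta and BMP signalling, 12 rose and 1 fell (12 and 2 adjusted over the list alone), including the activin receptor genes Acvr2a (0.45) and Acvr1 (0.31), Tgfb2 (0.32) and Smad3 (0.31). The list passed camera (adjusted p = 0.0258; adjusted p = 0.658 with an estimated correlation), but the adjusted p was 0.0532 without control replicate 1 and 0.0660 without Cugbp1 siRNA replicate 3. With centred arrays 4 were called higher and 2 lower. In the unfolded protein and integrated stress response list 8 of 32 rose and 1 fell (8 and 1 adjusted over the list alone), with Ddit4 at 0.54 and the cystine transporter gene Slc7a11 at 0.33 (camera, adjusted p = 0.188; median 0.08, and -0.02 with 3 higher and 3 lower with centring). Markers of haematopoietic, endothelial, epithelial and neural cells, which myoblasts are not known to express, were lower: 8 of 16 fell and 1 rose (10 and 1 adjusted over the list alone), including the macrophage gene Csf1r (-0.35), the integrin gene Itgam (-0.33) and the keratin genes Krt5 (-0.34) and Krt14 (-0.25). This list passed camera too (adjusted p = 5.67e-04; adjusted p = 0.0703 with an estimated correlation), and 11 were called lower with centred arrays.

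Of 27 myogenic regulators, 12 rose and 2 fell (12 and 2 adjusted over the list alone), led by Notch1 (0.66), the fusion protein gene Mymk (0.54) and the Notch target genes Hey1 (0.54) and Hes1 (0.33). Camera did not call the list (adjusted p = 0.283; 7 higher and 4 lower with centring). Of 44 sarcomere and differentiation genes, 9 rose and 10 fell (9 and 10 adjusted over the list alone), such as Neb (0.41), Sgca (0.35), Actn2 (-0.43) and the ubiquitin ligase gene Trim63 (-0.38; camera, adjusted p = 0.0604). The falls outnumbered the rises with other scalings, 16 against 4 with repeated normalisation and 18 against 3 with centring. Of 57 cell cycle and replication genes, 4 rose and 5 fell (1 and 4 adjusted over the list alone), Ccne1 by -0.28 (camera, adjusted p = 0.188, direction down although the mean was 0.00; median 0.00, and -0.10 with 23 lower with centring). Of 36 immediate-early genes, 11 rose and 3 fell (11 and 3 adjusted over the list alone), with Myc at 0.35 and Ccn1 at -0.37 (camera, adjusted p = 0.867; median 0.04, and -0.04 with 5 higher and 7 lower with centring). Of 36 matrix genes, 7 rose and 3 fell (7 and 3 adjusted over the list alone), with Col6a1 at 0.39 and Eln at -0.38 (camera, adjusted p = 0.746, direction down although the mean was 0.03; median 0.00, and -0.10 with 6 higher and 9 lower with centring). The last 3 lists were not called by camera. Of 25 p53 targets, 5 rose and 2 fell (4 and 2 adjusted over the list alone), with Sesn1 at 0.36 and Fas at -0.31 (0.02 without the filter). The adjusted p was 0.746, with the direction down although the median was 0.02, and -0.08 with 2 higher and 7 lower with centring. Of 22 interferon response genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone): Trim25 (0.23), Tlr3 (0.19), Oasl1 (-0.31) and Ccl2 (-0.18). The adjusted p was 0.943, with the direction down although the median was 0.08, and -0.02 with 3 lower with centring. Of 10 adipocyte and osteoblast markers, 1 rose and 2 fell (2 and 4 adjusted over the list alone), with Lpl at 0.48 (adjusted p = 0.283; 1 higher and 5 lower with centring).

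The comparison of Mbnl1 siRNA with control asks the same for that siRNA, with the same limit for MBNL1. Aspn rose by 1.74 (SE 0.12; limma with Benjamini-Hochberg, adjusted p = 1.49e-05) and the ferroxidase gene Cp by 1.59 (SE 0.12, adjusted p = 1.73e-05). Enpp2, which makes the signalling lipid lysophosphatidic acid, rose by 1.59 (SE 0.09, adjusted p = 4.42e-06) and Rgs2, a brake on G protein signalling, by 1.35 (SE 0.08, adjusted p = 5.21e-06). The serine protease gene Tmprss11f rose by 1.31, the tetraspanin gene Cd53 by 1.27 and Fam171b by 1.24. The matrix protein gene Spon2 rose by 1.23, Car3, a carbonic anhydrase abundant in slow muscle, by 1.21 and Nxf7 by 1.16. Besides Mbnl1, the cyclin-dependent kinase gene Cdk6 fell by 0.77 (SE 0.06, adjusted p = 1.67e-05, on 24 probe sets) and the keratin gene Krt80 by 0.83 (SE 0.05, adjusted p = 9.63e-06, on 13 probe sets). The other large falls were in Rspo2 (-0.92), Iba57 (-0.91), Eomes (-0.91), T (-0.72), Apoa4 (-0.71), Fam155a (-0.70) and Lypd9 (-0.68). Krt80 and these 7 also fell after Cugbp1 siRNA, by -0.59 (T) to -0.85 (Eomes). None of them was called between the siRNAs (limma with Benjamini-Hochberg, adjusted p from 0.230 to 0.906), so these falls are not particular to Mbnl1 siRNA. These 7, and the rises of Aspn, Rgs2, Tmprss11f and Nxf7, rest on 3 or 4 probe sets each, and Rspo2 reversed to 0.03 without the filter on weak signals. The controls of Aspn (6.86 ± 0.20), Cp (6.82 ± 0.20), Tmprss11f (6.78 ± 0.12), Spon2 (6.80 ± 0.02) and Nxf7 (6.83 ± 0.19), and Iba57 after Mbnl1 siRNA (6.90 ± 0.18, n = 3), lay below the filter's threshold, so the size of these changes is uncertain.

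In all, limma with Benjamini-Hochberg called 5245 of 12646 genes after Mbnl1 siRNA, 3397 higher and 1848 lower, with a median size of 0.27. At least 1.5-fold changes numbered 207 (176 higher and 31 lower). The arrays did not overlap in 57.5% of genes, against 10% by chance. As for Cugbp1 siRNA, the balance turned with the scaling, to 2004 higher and 3395 lower with quantile normalisation repeated and 1716 and 3918 with centring.

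Matrix genes had the smallest camera p of the lists after Mbnl1 siRNA. Of 36 members, 24 rose and 1 fell (24 and 2 adjusted over the list alone), including Postn (1.05, SE 0.09), Vcan (0.79, SE 0.05), Fbn1 (0.65, SE 0.05) and Tnc (0.59, SE 0.05). The list passed camera (adjusted p = 1.36e-04; adjusted p = 0.383 with an estimated correlation), and 18 were called higher and 3 lower with centred arrays. Of 26 genes of TGF-beta and BMP signalling, 17 rose and 1 fell (17 and 2 adjusted over the list alone), including Tgfb2 (0.53), Acvr2a (0.44) and Tgfb3 (0.41; camera, adjusted p = 0.00774, and adjusted p = 0.480 with an estimated correlation; 10 higher and 5 lower with centring). Of 57 cell cycle and replication genes, 10 fell and 1 rose (8 fell adjusted over the list alone). Besides Cdk6 these included the cyclin gene Ccnd1 (-0.33), the phosphatase gene Cdc25a (-0.27) and the repressor gene E2f7 (-0.25). Camera called the list lower (adjusted p = 0.00774; adjusted p = 0.587 with an estimated correlation, 0.109 without the filter and 0.103 with fry). More were called lower with other scalings, 23 with repeated normalisation and 31 with centring. Of the 48 other splicing regulators, 21 rose and 3 fell (26 and 3 adjusted over the list alone), such as Khdrbs3 (0.57), Tia1 (0.40) and Ddx17 (0.32; camera, adjusted p = 0.00672, and adjusted p = 0.587 with an estimated correlation; 4 higher and 3 lower with centring). Of the 64 genes with exons regulated in myotonic dystrophy, 34 rose and 5 fell (39 and 5 adjusted over the list alone), such as Itga6 (0.48), Sorbs2 (0.47) and the dystrobrevin gene Dtna (0.41; camera, adjusted p = 0.00865, and adjusted p = 0.581 with an estimated correlation; 13 higher and 12 lower with centring).

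The remaining lists were not called by camera after Mbnl1 siRNA. In the CELF and MBNL family, 3 of 9 rose and 5 fell (3 and 5 adjusted over the list alone), Celf6 by -0.50 and Mbnl3 by -0.38 (adjusted p = 0.0525, and 1 higher and 5 lower with centring). In cholesterol synthesis and uptake, 5 of 21 fell and 1 rose (5 and 1 adjusted over the list alone), including the SREBP genes Srebf1 (-0.26) and Srebf2 (-0.19; adjusted p = 0.0632; 9 lower with centring). In the unfolded protein and integrated stress response, 10 of 32 rose (10 adjusted over the list alone), with Ddit4 at 0.46 and Aldh1l2 at 0.40 (adjusted p = 0.0632; 6 higher and 3 lower with centring). Of the decay genes, 16 of 53 rose and 2 fell (15 and 1 adjusted over the list alone), with Xrn1 at 0.84 and Zfp36l1 at 0.53 (adjusted p = 0.124; median 0.09, and -0.02 with 7 higher and 11 lower with centring). Markers of haematopoietic, endothelial, epithelial and neural cells went both ways, 3 of 16 higher and 5 lower (3 and 5 adjusted over the list alone), with Cd68 at 0.49, Map2 at 0.40 and Pecam1 at -0.42 (adjusted p = 0.0676; 2 higher and 9 lower with centring). Of the muscle lists, 8 of 27 myogenic regulators rose and 5 fell (9 and 6 adjusted over the list alone), with Hey1 at 0.57 and Mef2a at 0.31 (adjusted p = 0.796, direction down although the median was 0.03, and -0.08 with 4 higher and 11 lower with centring). Of the sarcomere genes, 8 of 44 rose and 8 fell (7 and 7 adjusted over the list alone), with Neb at 0.45, Tnnt2 at 0.35 and Actn2 at -0.33 (adjusted p = 0.231, with a median of -0.03 and a mean of 0.00). The falls outnumbered the rises with other scalings, 16 against 3 with repeated normalisation and 19 against 3 with centring. Of 36 immediate-early genes, 14 rose and 3 fell (14 and 3 adjusted over the list alone), with Gadd45a at 0.57 and Dusp6 at 0.48 (adjusted p = 0.654; median 0.00, and -0.08 with 11 higher and 14 lower with centring). Of 25 p53 targets, 6 rose and 2 fell (5 and 2 adjusted over the list alone), with Sesn1 at 0.49 and Fas at -0.40 (adjusted p = 0.976, with a median of -0.01 and a mean of 0.04; 3 higher and 7 lower with centring). Of 22 interferon response genes, 9 rose and 2 fell (9 and 2 adjusted over the list alone), with Tlr3 at 0.45 and Ccl2 at -0.38 (adjusted p = 0.372; median 0.10, and -0.02 with 2 higher and 2 lower with centring). Of 10 adipocyte and osteoblast markers, 3 rose and 4 fell (3 and 5 adjusted over the list alone), with Lpl at 0.33 and Sp7 at -0.30 (adjusted p = 0.360; 2 higher and 6 lower with centring).

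Many genes moved the same way after either siRNA. Acp1 (1.01 and 1.05), Prr9 (1.5 and 0.92), Nmnat2 (1.2 and 0.91), Aspn (1.23 and 1.74) and Xrn1 (0.84 and 0.84) rose after Cugbp1 siRNA and after Mbnl1 siRNA. In the same order, Eomes (-0.85 and -0.91), Rspo2 (-0.80 and -0.92), Iba57 (-0.73 and -0.91), Lypd9 (-0.76 and -0.68) and Krt80 (-0.72 and -0.83) fell after both. Of the genes called against control, 2236 were higher in both comparisons and 1154 lower in both, against 885 and 234 for independent lists of these sizes, and 66 went opposite ways, against 911. The changes correlated across genes (r = 0.789; genes are not independent replicates), and 81.3% had the same sign. Unchanged groups that shared the controls gave a median r of 0.520 (-0.738 to 0.980 in 100 simulations) and a median of 67.8% of the same sign. The highest share was 93.9%, so neither the r nor the share of signs lay outside what unchanged groups gave. The covariance was 0.0356, against a simulated median of 0.0025 and a highest value of 0.0129. The 3 controls are too few to be split, so what sharing them adds was only simulated.

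**Figure D3:**
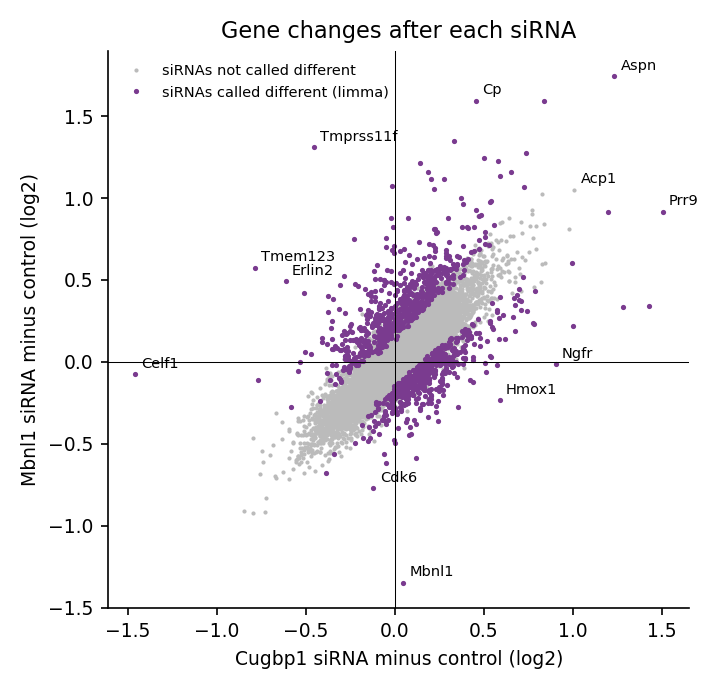
Change of each of the 12646 genes after Cugbp1 siRNA (x axis) and after Mbnl1 siRNA (y axis), log2 against control; purple points are the 1181 genes whose response differed between the siRNAs in limma. Most genes lie along the diagonal, with Celf1 at the far left, Mbnl1 at the bottom, and Tmem123, Erlin2 and Tmprss11f in the upper left.

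The direct comparison of the siRNAs asks which genes respond differently to them, and it does not use the controls as a reference. The sources used here do not say how many siRNAs were used per target or whether off-target effects were controlled. Effects of an siRNA on RNAs other than its target therefore cannot be told apart from loss of CELF1 or MBNL1. Tmem123 had the smallest p: it was lower after Cugbp1 siRNA than after Mbnl1 siRNA (-1.36, SE 0.04; limma with Benjamini-Hochberg, adjusted p = 2.65e-07), with 9.91 ± 0.07 after Cugbp1 siRNA, 10.69 ± 0.01 in controls and 11.27 ± 0.03 after Mbnl1 siRNA (n = 3). Erlin2, a protein of the endoplasmic reticulum membrane, behaved alike (-1.10, SE 0.05, adjusted p = 2.6e-06), at -0.61 after Cugbp1 siRNA and 0.49 after Mbnl1 siRNA. Cp differed by -1.14. Tmprss11f was lower too, but it stood below the filter's threshold after Cugbp1 siRNA (6.33 ± 0.34) and in controls, against 8.10 ± 0.15 after Mbnl1 siRNA (n = 3), so the size of its difference is uncertain. Ngfr was higher after Cugbp1 siRNA (0.92, SE 0.08, adjusted p = 8.77e-05), as was the haem oxygenase gene Hmox1 (0.82, SE 0.06, adjusted p = 7.11e-05), which was at 0.59 after Cugbp1 siRNA and -0.23 after Mbnl1 siRNA. H4c12 (1.09) differed the same way, beside the targets Mbnl1 (1.39) and Celf1 (-1.39). Limma with Benjamini-Hochberg called 1181 of 12646 genes, 540 higher after Cugbp1 siRNA and 641 higher after Mbnl1 siRNA, and 59 by at least 1.5-fold (12 and 47). Arrays did not overlap in 29.5% of genes, against 10% by chance. Of the 1181, 323 were called against control after Cugbp1 siRNA alone, 481 after Mbnl1 siRNA alone, 216 after both in the same direction, 66 in opposite directions and 95 after neither. The count was 755 without Cugbp1 siRNA replicate 2, and 679, 632 and 690 without Mbnl1 siRNA replicate 1, 2 or 3; it was 639 without the filter and 2767 with array weights.

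Cholesterol and matrix genes parted most clearly between the siRNAs. Of 21 cholesterol genes, 10 were higher after Cugbp1 siRNA than after Mbnl1 siRNA (14 adjusted over the list alone), including Lss (0.40, SE 0.04), Srebf1 (0.31), Fdps (0.26) and Srebf2 (0.24). Camera's adjusted p was 6.28e-10, and the call held with an estimated correlation (adjusted p = 0.00613), the only list for which it did. Of 36 matrix genes, 14 were lower after Cugbp1 siRNA than after Mbnl1 siRNA (21 adjusted over the list alone), including Tnc (-0.69, SE 0.05), Fbn1 (-0.57), Vcan (-0.55) and Thbs2 (-0.33; camera, adjusted p = 1.05e-12, and adjusted p = 0.0831 with an estimated correlation). The direction of both lists was the same under each scaling.

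**Figure D4:**
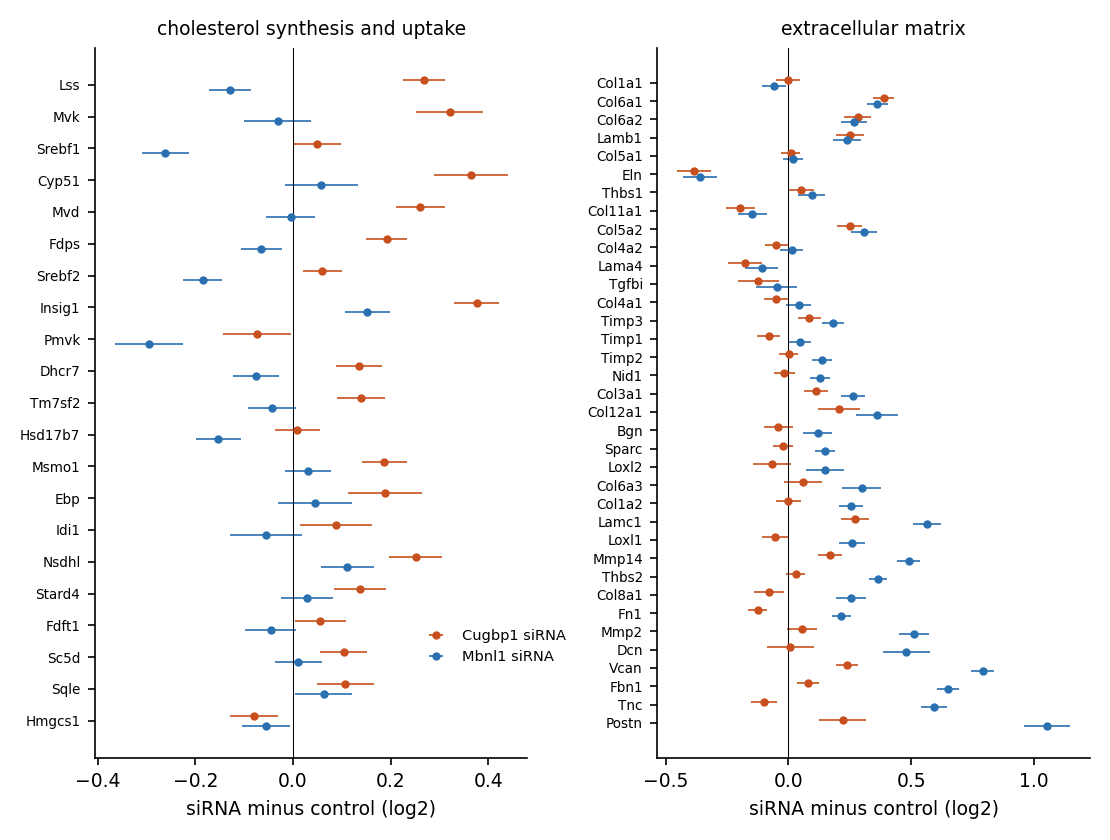
Change of the 21 measured cholesterol genes and 36 matrix genes after each siRNA (log2 against control, with SE), ordered by the difference between the siRNAs. Cholesterol genes lie higher after Cugbp1 siRNA (median difference 0.18) and matrix genes higher after Mbnl1 siRNA (median difference -0.15); both differences keep their direction under each scaling, while the matrix median after Cugbp1 siRNA against control turns from 0.00 to -0.10 with centring.

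Another 4 lists passed camera in the direct comparison. Cell cycle genes were higher after Cugbp1 siRNA, 7 of 57 (7 adjusted over the list alone), including Cdk6 (0.65), Ccnd1 (0.27) and Cdc25a (0.24; adjusted p = 0.0320, and adjusted p = 0.725 with an estimated correlation). That call was lost without Cugbp1 siRNA replicate 3 (adjusted p = 0.187), Mbnl1 siRNA replicate 1 (0.0627) or replicate 2 (0.0756). Myogenic regulators were higher, 6 of 27 (6 higher and 1 lower adjusted over the list alone), including Mymk (0.51) and Notch1 (0.39; adjusted p = 0.0358, and adjusted p = 0.699 with an estimated correlation), but not without control replicate 3 (0.0511), Cugbp1 siRNA replicate 1 (0.0654) or 3 (0.0836) or Mbnl1 siRNA replicate 2 (0.168). The genes with exons regulated in myotonic dystrophy were lower after Cugbp1 siRNA than after Mbnl1 siRNA, 9 of 64 with 3 higher (10 and 3 adjusted over the list alone), including Sorbs2 (-0.78), Macf1 (-0.37) and Fn1 (-0.34; adjusted p = 0.0251, and adjusted p = 0.725 with an estimated correlation; 0.0654 without Cugbp1 siRNA replicate 1). Markers of haematopoietic, endothelial, epithelial and neural cells were lower, 5 of 16 (5 adjusted over the list alone), including Cd68 (-0.53) and Map2 (-0.25; adjusted p = 0.0358, and adjusted p = 0.199 with an estimated correlation; 0.0581 without control replicate 3, 0.252 without Cugbp1 siRNA replicate 3 and 0.0589 without Mbnl1 siRNA replicate 2). In lists without a call, the deadenylase gene Parn (0.36), the exosome nuclease gene Dis3 (0.33) and the fetal acetylcholine receptor subunit gene Chrng (0.54) were higher after Cugbp1 siRNA, and Ccn2 (-0.44) and Ltbp1 (-0.37) were lower.

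Both proteins regulate splicing, and the exon arrays ask whether probe sets departed from the rest of their gene. Against control, diffSplice with Benjamini-Hochberg called 11709 of 158713 probe sets in 6260 genes after Cugbp1 siRNA and 17155 in 7527 genes after Mbnl1 siRNA. Among those with the smallest p after Cugbp1 siRNA were probe sets in Agrn (relative log2 -1.69), Armcx3 (-1.54), Dhx29 (-1.49), Yy1 (-1.42), Me1 (-1.11) and Hcfc1 (-1.10), and in Celf1 itself (1.92), where this probe set rose by 0.56 while its gene fell. Other Celf1 probe sets fell by less than the gene, such as those at -0.26, -0.35 and -0.42, though 20 of 25 fell at least 2-fold. After Mbnl1 siRNA they were in Dnm2 (1.41), Fn1 (0.84), Npnt (-2.02), Yy1 (-1.66), Pcbp2 (-1.64), Col18a1 (-1.45), Vcan (-1.42) and Caprin1 (-1.19). Others with a small p lay below the filter's threshold in a group, so their sizes are not given: Trrap (5.85 ± 1.38 in controls) in both comparisons, Snx12 (6.27 ± 0.17 in controls) and Fasn (6.77 ± 0.40 after Cugbp1 siRNA) in the first, and Mbnl1 itself (6.84 ± 0.41 in controls, n = 3) in the second. Of 7975 probe sets called in both comparisons, 7965 went the same way. Both comparisons use the same controls, which alone push shared calls to the same sign, and no simulation of that was made for probe sets. The first count was 7718 without control replicate 3 and 7316 without Cugbp1 siRNA replicate 3, and the second 9537 without Mbnl1 siRNA replicate 3. With the probe sets in 3 equal groups by intensity, the brightest group was called 0.291 times as often as the dimmest after Cugbp1 siRNA, and 0.355 times as often after Mbnl1 siRNA. In data simulated for Cugbp1 siRNA against control, 493 of 691 diffSplice calls were in genes with no change, and 142 of 311 under the second noise model. Few genes and probe sets were changed in that simulation, so the share of false calls does not carry over to these counts.

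Limma on each probe set's own variance, a test added after the data were seen, called 8104 after Cugbp1 siRNA, 5939 of them shared with diffSplice, but 4058 without control replicate 3 and 4279 and 3313 without Cugbp1 siRNA replicate 2 or 3. After Mbnl1 siRNA it called 15147, with 10907 shared, but 8327 without control replicate 3 and 7156, 8454 and 5563 without Mbnl1 siRNA replicate 1, 2 or 3. Genes with exons regulated in myotonic dystrophy, such as Map4k4 (-1.11), Itga6 (-0.88), Opa1 (-0.86) and Ryr1 (-1.07) after Cugbp1 siRNA and Itga6 (-1.15), Tjp1 (-1.15) and Dtna (-1.07) after Mbnl1 siRNA, were not called more often than drawn genes beyond chance. By diffSplice the counts were 48 of 64 after Cugbp1 siRNA, with a median of 47 expected (permutation p = 0.385), and 50 after Mbnl1 siRNA, with 53 expected (permutation p = 0.883). By own variance they were 41 with 40 expected (permutation p = 0.401) and 53 with 51 expected (permutation p = 0.319).

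Between the siRNAs fewer probe sets were called for exon usage. In Myl6, a myosin light chain gene with an alternative exon, 1 probe set stood at 11.64 ± 0.04 in controls, 12.16 ± 0.11 after Cugbp1 siRNA and 10.94 ± 0.10 after Mbnl1 siRNA (n = 3), while the gene as a whole did not pass (0.06, adjusted p = 0.496). Its relative difference was 1.17 (SE 0.06; limma on the probe set's own variance with Benjamini-Hochberg, adjusted p = 1.77e-07). A probe set in the matrix gene Npnt stood at 9.75 ± 0.13, 9.32 ± 0.22 and 7.87 ± 0.46 in the same order (1.71, SE 0.15, adjusted p = 9.64e-05), and one in Mia2 at 7.31 ± 0.21, 8.53 ± 0.32 and 6.85 ± 0.06 (1.74, SE 0.16, adjusted p = 9.64e-05), the last below the filter's threshold. A probe set of the kinase gene Wnk1 was relatively higher after Mbnl1 siRNA (-1.08), as were probe sets in Dnm2 (-1.13), Fgfr1 (-0.69), Mpdz (-0.83) and Sec31a (-0.93). Probe sets in Col6a3 (1.21), Ndrg4 (1.34) and Pkm (0.77), the pyruvate kinase gene, were relatively lower after Mbnl1 siRNA. In Tor1aip2 a probe set moved with Cugbp1 siRNA instead (-0.97), at -0.79 against control after Cugbp1 siRNA and 0.18 after Mbnl1 siRNA. These probe sets were chosen after their values were seen, and each kept its call in this test with any single array left out.

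**Figure D5:**
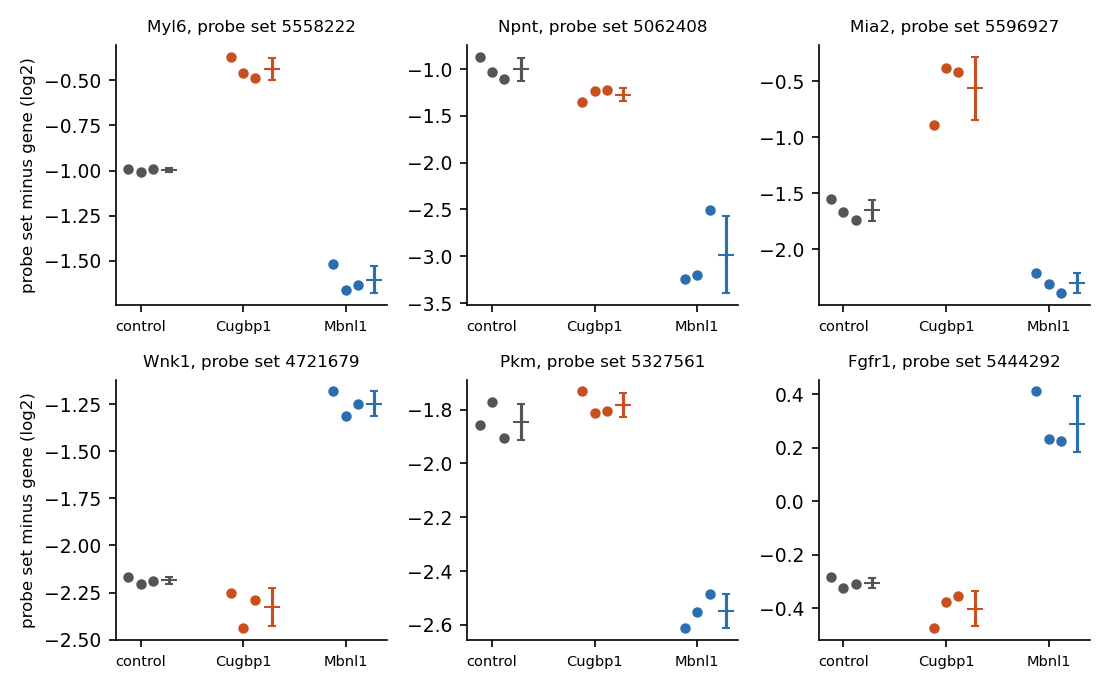
Log2 intensity of single probe sets minus the value of their gene on each array, for 6 genes, with the mean and SD of each group of 3 beside the points. In Myl6 the 3 groups part, with Cugbp1 siRNA above and Mbnl1 siRNA below the controls; in Npnt, Wnk1, Pkm and Fgfr1 the Mbnl1 siRNA arrays stand apart.

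In this comparison diffSplice with Benjamini-Hochberg called 554 probe sets in 454 genes, 241 relatively higher and 313 relatively lower after Cugbp1 siRNA. That balance turned without Mbnl1 siRNA replicate 3 (133 and 120) and by own variance (75 and 47). The smallest p by diffSplice were in Myl6, Mbnl1, Npnt, Celf1, Mia2, Dnm2, Wnk1, Fn1, Ndrg4 and Nasp. The count was 369 and 836 without Cugbp1 siRNA replicate 1 or 3, and 320, 337 and 253 without Mbnl1 siRNA replicate 1, 2 or 3. In data simulated for Cugbp1 siRNA against control, diffSplice made 493 or 142 calls in genes with no change, by noise model. Many of the 554 may therefore be false. Limma on each probe set's own variance called 122 in 87 genes, 91 of them shared with diffSplice, with 8 in Mbnl1 and 4 in Celf1. Against control, 73 of the 122 were called after Mbnl1 siRNA alone, 28 after Cugbp1 siRNA alone and 16 after both. The 122 became 79 and 57 without Cugbp1 siRNA replicate 1 or 2, and 62, 45 and 65 without Mbnl1 siRNA replicate 1, 2 or 3. Genes with exons regulated in myotonic dystrophy were over-represented: 16 of 64 by diffSplice, against a median of 5 expected (permutation p = 1e-04, the smallest 10000 draws can give), and 9 by own variance, against 1 expected (permutation p = 1e-04), or 8 without Mbnl1 itself. The draws matched the number of probe sets but not change at gene level. By diffSplice, 1.04% of probe sets were called in genes called at gene level, against 0.264% in other genes. At gene level 3 of the 64 were called higher and 9 lower, while 9.34% of all genes were called. The draws therefore cannot tell over-representation in exon usage from more frequent change at gene level. Of the 9 listed genes called by own variance, Mbnl1, Fn1 (-0.40) and Slain2 (0.70) kept a called probe set with any single array left out. The other 6 lost theirs. The largest adjusted p on leaving out an array was 0.104 for Nfix and 0.107 for Tead1 (both without Cugbp1 siRNA replicate 2) and 0.0613 for Ldb3 (without Mbnl1 siRNA replicate 3). It was 0.156 and 0.167 for 2 probe sets of Tjp1 (without Mbnl1 siRNA replicate 2), 0.275 for Itga6 (without Mbnl1 siRNA replicate 1) and 0.344 for Mbnl2 (without Mbnl1 siRNA replicate 2).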

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

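The counts of other splits of the arrays for exon usage between the siRNAs, the fit with a covariate and the own-variance test were chosen only after the results were seen.

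Both siRNAs moved the same genes in the same direction against control, and the covariance of the changes, 0.0356, exceeded the highest of 100 simulated pairs of unchanged groups that shared the controls (0.0129), which argues against shared controls alone. The test of a technical difference between the control arrays and the other 6 met the bound set before its value was seen, and that difference stays open. It used probe sets of tissue-restricted genes such as odorant receptors, which myoblasts are not known to express. Their covariance beyond that of shared controls was 0.790 times that of the other named probe sets. It was 0.626 times that of probe sets of like brightness, below the lowest of 100 draws (0.0523 against 0.0554). The 95% bootstrap interval of the 0.0523, from 0.0338 to 0.0723, includes that lowest draw. An interferon response to the siRNA duplexes cannot be told apart. The medians of the 22 listed genes were 0.0848 and 0.0990, and camera called the list after neither siRNA (adjusted p = 0.943 and 0.372). This met the bound set beforehand against such a response, a median under 0.1 in both and no camera call. A bootstrap over the genes, not the arrays and not part of that bound, gave the larger median a 95% interval of 0.01 to 0.21. That is too wide to exclude a rise of 0.1. With centred arrays both medians were -0.02. A covariate from the tissue-restricted probe sets ended every call against control (limma, 0 genes after either siRNA; 1543 and 1391 at an unadjusted p under 0.05): the median SE grew from 0.06 to 0.20 and 0.22, while the median size among the called genes went from 0.25 to 0.18 and from 0.27 to 0.20, and the covariate was itself 94.2% control against the rest. A biological response that both knockdowns share, or that any transfection with a targeting siRNA brings, remains possible and may add to a technical part, but it was not tested.

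More genes rose than fell after either siRNA in the values as deposited. The falls outnumbered the rises with quantile normalisation repeated (1650 higher and 2731 lower after Cugbp1 siRNA, 2004 and 3395 after Mbnl1 siRNA) and with each array centred on its median (1366 and 3206, 1716 and 3918). Weak signals that drift upwards are argued against, since with the genes in 3 equal groups by intensity, 84.0% and 79.9% of the called genes rose in the brightest group, and 43.4% and 42.9% in the dimmest. Whether the centring of the arrays made the excess cannot be told apart from a true excess: with the changes centred on the median gene 46.5% of 4280 and 50.8% of 5075 called genes rose, but such centring puts as many genes above 0 as below by construction. No biological explanation of the excess was tested.

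The probe sets called for exon usage against control were not confined to genes called at gene level. The rate in genes not called at gene level was at least 0.788 times the rate in called genes. This passed the bound set beforehand against an uneven response of probe sets to changes in total level as the whole source. The ratio cannot settle it, since in simulated data diffSplice also made calls in genes with no change, which would raise the ratio. Genes not called may have changed too, as the gene test recovered 32.8% of simulated 1.2-fold changes under the first noise model. Probe sets near the detection limit are a candidate source: the brightest of 3 equal groups was called 0.291 and 0.355 times as often as the dimmest. Between the siRNAs the first of these ratios was 0.254 and the second 0.217, so there an uneven response stays open too. Altered splicing after loss of either protein stays open beside these and was not tested on transcripts.

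For each comparison 10 splits of 3 against 3 arrays can be made, too few for a share under 0.05, and in each of them only 1 split, the real one, gave as many calls. In the 2-group fits the real split called 3944 genes for Cugbp1 siRNA against control, 5632 for Mbnl1 siRNA against control and 859 between the siRNAs, and the highest other split 0 in limma (508, 228 and 665 at an unadjusted p under 0.05). For exon usage the real splits called 8711, 18854 and 739 probe sets and the highest others 158, 165 and 92. Every other split mixes arrays of both groups, which puts the difference between the groups into its spread. The few calls there therefore do not show what unchanged groups would give.

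Several results differed between the siRNAs by a test of the difference itself. They were the 1181 genes, the 554 probe sets for exon usage by diffSplice (122 with each probe set's own variance) and 6 gene lists by camera. With an estimated correlation only cholesterol synthesis and uptake kept its call (adjusted p = 0.00613), and the adjusted p of the others ran from 0.0831 to 0.725. The median differences (Cugbp1 siRNA minus Mbnl1 siRNA) of these lists were 0.182 for cholesterol synthesis and uptake, 0.0498 for cell cycle and DNA replication, 0.0432 for myogenic regulators, -0.152 for extracellular matrix, -0.0605 for haematopoietic, endothelial, epithelial and neural markers and -0.0447 for genes with exons regulated in myotonic dystrophy. The gene count was 755 without Cugbp1 siRNA replicate 2 and 679, 632 and 690 without Mbnl1 siRNA replicate 1, 2 or 3. The probe set count was 369 and 836 without Cugbp1 siRNA replicate 1 or 3 and 320, 337 and 253 without Mbnl1 siRNA replicate 1, 2 or 3. In data simulated for Cugbp1 siRNA against control, diffSplice made 493 or 142 calls in genes with no change, by noise model. Lists past the threshold numbered 3 without Cugbp1 siRNA replicate 3 and 3 without Mbnl1 siRNA replicate 2.

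Signals also appeared in probe sets with no gene name, which no comparison above uses. Of 130086 above the filter, limma called 13281 after Cugbp1 siRNA, 5354 of them higher than in control, and 19004 after Mbnl1 siRNA, 8264 of them higher. The shares of rises were 40.3% and 43.5%, against 72.7% and 72.5% among the called probe sets with a name. These sets were not matched for brightness, and the filter kept 14.8% of the unnamed against 53.3% of the named ones. Among called genes the share of rises itself went from 43.4% and 42.9% in the dimmest group to 84.0% and 79.9% in the brightest. Between the siRNAs 16 were called (0.0123%), against 0.758% of the probe sets with a name.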

How the results depend on the processing

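The own-variance and 1.5-fold tests of exon usage, all runs of exon usage between the siRNAs, the covariate and the lists without the siRNA targets were chosen only after the results were seen. Both targeted genes kept their fall with the replicate number as a block, with the mean of the probe sets (-1.28 for Celf1 and -1.07 for Mbnl1) and with no filter (-1.28 and -1.20). With each array left out in turn, Celf1 was at -1.52 to -1.43 and Mbnl1 at -1.41 to -1.32. Over the same runs, Cugbp1 siRNA against control gave 3498 to 5523 genes, 7316 to 11596 probe sets for exon usage and 5 to 7 gene lists. Mbnl1 siRNA against control gave 3899 to 6025 genes, 9537 to 20021 probe sets and 5 to 6 lists. The genes changed the same way by both numbered 2518 to 3958. Between the siRNAs there were 632 to 1155 genes, 253 to 836 probe sets and 3 to 6 lists.

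A minimum change of 1.5-fold left 108 genes after Cugbp1 siRNA, 207 after Mbnl1 siRNA, 59 between the siRNAs and 55 changed the same way by both, and 4804, 7021 and 334 probe sets for exon usage. It removes small changes by construction. With the genes called at gene level left out, whatever the size of the change in exon usage, 6116, 8277 and 293 probe sets were called. Between the siRNAs, 639 genes were called without the filter on weak signals and 2767 with array weights, which ran from 0.296 for Cugbp1 siRNA replicate 1 to 3.71 for replicate 2. Exon usage between the siRNAs gave 1088 probe sets with the filter at the median and 122 with each probe set's own variance. With an estimated correlation camera called 0 lists after Cugbp1 siRNA, 0 after Mbnl1 siRNA and 1 between the siRNAs (2, 0 and 3 at an unadjusted p under 0.05), and fry called 10, 10 and 3. Without the targets Celf1 and Mbnl1 camera called 5, 5 and 6 lists, and the CELF and MBNL family lost its call after Cugbp1 siRNA (adjusted p = 0.177). With the covariate from tissue-restricted genes limma called 0 genes after either siRNA (1543 and 1391 at an unadjusted p under 0.05) and 1001 between them. The covariate is nearly the contrast with the controls, and with it even the targeted Celf1 (-1.72, adjusted p = 0.112) and Mbnl1 (-1.56, adjusted p = 0.144) missed the threshold. The cause of the other shifts was not tested.

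Among values of the 222 named calls, 4028 of 4625 kept their direction and their call, 569 kept only the direction and 28 reversed; for the 17 called lists 202 of 238 kept both and 36 the direction. Without the filter Fas turned to 0.0182 after Cugbp1 siRNA, and after Mbnl1 siRNA Rspo2 to 0.0331 and Tnni2 to 0.0202; Tnni2 was at 0.00127 with the filter at the median. With the covariate the values after Cugbp1 siRNA were Acvr2a -0.0318, Aldh1l2 -0.0164, Csf1r 0.00561, Cyp51 -0.149, Ddx5 -0.0365, Ect2 -0.0281, Eln 0.116, Hey1 -0.299, Krt5 0.203, Mfap4 0.319, Neb -0.28, Plk1 0.119, Polk -0.043 and Vcan -0.00241. After Mbnl1 siRNA they were Acvr2a -0.099, Aldh1l2 -0.00492, Btg2 -0.229, Csf1r 0.0485, Hey1 -0.378, Id2 -0.00615, Neb -0.329, Phex -0.0743, Tardbp -0.102 and Tnni2 0.141. The covariate was 94.2% control against the rest, nearly the contrast itself, and with it the median SE was 0.20 and 0.22. The signs of these values under the covariate are therefore uncertain. The cause of the reversals with other filters was not tested.

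The samples share only a number across groups. With that number as a block, 4539, 4982 and 875 genes and 11214, 16685 and 488 probe sets were called, with 6, 5 and 6 lists and 3156 genes changed the same way. In the check of pairs, 1 of 9 correlations between arrays of the same number exceeded 0.1 (-0.101 to 0.124). Those between arrays of different numbers ran from -0.130 to 0.0925, and 5 of 9 arrays matched best with an array of their own number. The ranges largely overlap, so this does not show a pairing, and the labels give none. Signal over background limits weak genes: the filter kept 53.3% of the probe sets with a name. Among the named falls after Cugbp1 siRNA, Abca12, Eomes, Rspo2 and Slc25a47, with 3 or 4 kept probe sets each, lost their calls without it. Eomes stood at 11.31 ± 0.11 in controls (n = 3) on its 3 kept probe sets, far above the threshold. A weak gene value therefore does not account for its loss. Why adding its weaker probe sets ended the call was not tested. The planned test of motifs in 3' UTRs was not run.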

Other observations

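All gene families in this part were chosen after the data were seen, so their tests describe these data only. The ectonucleotide pyrophosphatases are membrane and secreted enzymes that split nucleotides and lysophospholipids. After Mbnl1 siRNA, 4 of 5 measured members rose: Enpp2 (1.59), Enpp1 (1.16), Enpp3 (1.14) and Enpp4 (0.31; camera over 17 families, adjusted p = 0.00211, and adjusted p = 0.168 with an estimated correlation). After Cugbp1 siRNA, Enpp2 (0.84), Enpp1 (0.65) and Enpp3 (0.59) rose without a call of the family (adjusted p = 0.0505, and adjusted p = 0.298 with an estimated correlation), and between the siRNAs the same 3 differed by -0.75, -0.50 and -0.55 (camera, adjusted p = 2.37e-05, and adjusted p = 0.102 with an estimated correlation). The serpins, mostly inhibitors of serine proteases, were lower after Cugbp1 siRNA than after Mbnl1 siRNA in 5 of 15, including Serpinb9b (-0.48), Serpinb2 (-0.41) and Serpinb9 (-0.27), while Serpinb8 was higher (0.34; camera, adjusted p = 0.00943, and adjusted p = 0.210 with an estimated correlation). Both families kept their direction in these comparisons under each scaling.

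Of 39 genes for subunits and assembly factors of respiratory complex I, 6 were called higher after Cugbp1 siRNA than after Mbnl1 siRNA, including Ndufaf5 (0.36), Ndufa8 (0.25), Ndufa9 (0.22) and Ndufa10 (0.21; camera, adjusted p = 7.85e-05, and adjusted p = 0.127 with an estimated correlation). Of 75 mitochondrial ribosomal protein genes, 9 were called higher, including Mrps35 (0.29), Mrpl50 (0.25) and Mrpl38 (0.25; camera, adjusted p = 7.85e-05, and adjusted p = 0.210 with an estimated correlation). Against control, 15 of 39 complex I genes rose after Cugbp1 siRNA, with Ndufb8 at 0.28 (camera, adjusted p = 0.0139, and adjusted p = 0.298 with an estimated correlation), though with centred arrays 1 was called higher and 1 lower. Of the 75 mitochondrial ribosomal protein genes 28 rose and 2 fell, with rises such as Mrpl1 (0.49) and Mrps31 (0.40; camera, adjusted p = 0.00565, and adjusted p = 0.403 with an estimated correlation; 12 higher and 6 lower with centring). After Mbnl1 siRNA the medians were 0.03 and 0.06 and turned to -0.08 and -0.04 with centring.

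Keratin genes, which belong to epithelia, had medians of -0.15 after Cugbp1 siRNA and -0.16 after Mbnl1 siRNA. That is no larger than the fall in other genes that myoblasts are not known to express. The median was -0.18 after either siRNA for the tissue-restricted probe sets, and -0.24 and -0.21 for olfactory receptor genes. The olfactory receptor genes were not among the 17 families tested, and after either siRNA only 2 were called lower, or 4 with centring. Odorant receptors are also part of the tissue-restricted set, so these medians are not separate comparisons. Of 31 measured, 13 fell and 1 rose after Cugbp1 siRNA, including Krt80 (-0.72), Krt2 (-0.47), Krt83 (-0.43) and, higher, Krt13 (0.58; camera, adjusted p = 8.86e-08, and adjusted p = 0.109 with an estimated correlation). After Mbnl1 siRNA 10 fell, including Krt80 (-0.83) and Krt2 (-0.58; camera, adjusted p = 7.2e-06, and adjusted p = 0.168 with an estimated correlation). Of 239 zinc-finger genes named Zfp, 93 rose and 10 fell after Cugbp1 siRNA, and 93 rose and 17 fell after Mbnl1 siRNA (camera, adjusted p = 0.00565 and 0.0206, and adjusted p = 0.465 and 0.8 with an estimated correlation; 52 and 24, and 54 and 37, with centring). Of 161 long non-coding RNA genes, 25 rose and 27 fell after Cugbp1 siRNA, and 28 rose and 28 fell after Mbnl1 siRNA.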
